A study of Mus musculus with 8 samples.

How the data were processed

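H3K27ac ChIP-seq libraries of 2 WT and 2 Bcl11bKO samples were compared. Per the labels' protocols, progenitors were sorted from lineage-depleted mouse bone marrow and cultured on OP9-DL1 stroma. On day 7 they were passed through a mesh and given 120 nM 4-hydroxytamoxifen for 2 days, then grown for 5 more days. The labels name no sort after culture. Chromatin of 10 M cells, fixed in 1% formaldehyde and sonicated for 18 cycles, was precipitated with 5 µg of antibody per 10 M cells and read as single 50 nt reads. Groups and replicate numbers were taken from the sample titles, and the labels give no batch. The 4 input samples were not used here.

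Reads were aligned with Bowtie 1.1.1 and peaks handled with HOMER on mouse build mm9, per the submitters' processing notes. Per the file headers, each deposited list is the output of HOMER's peak annotation for the peaks of 1 library, so replicates were not pooled. Whether the input served as a control is not given in the sources used here. The deposited signal per peak, in a column headed as a score, is a library-size normalised tag number. In each file 100% of the values were whole multiples of 1 step within the rounding of 0.05. The scale was taken to be tags per 10 M, HOMER's default, which the headers do not state, and under it the library totals were 23.2 to 33.3 M. No peak lay under 15 normalised tags (35 to 50 whole tags per library). A region without a peak has an unknown value, not 0. Whether that value lies under the floor of 15 is not known either, since the filters used in peak calling are not given. Counting alone gives a standard deviation of the log2 difference of 0.12 to 0.13 between libraries at a median region. Lists called separately differ in covered length, which enters every sum and is given beside some of them only.

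Peaks of the 4 lists sharing at least 1 base were merged into 44718 regions, and a region counted as called in a library with a peak in it. Regions called in all 4 libraries were tested with limma 3.58.1 (R 4.3.3) on log2 of summed tags plus 1, by group alone. Genes were tested with limma's trend option on log2 of tags plus 10, summed over peaks whose nearest start site, as the files name it, lay within 100 kb, for genes with a peak in at least 2 libraries. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. With 2 libraries per group an exact permutation test cannot go below p = 0.33, so single comparisons rest on the spread that limma pools over regions or genes. Gene and region names, coordinates and features are those of the files; 37214 regions had a named gene within 100 kb. Fold changes are on the log2 scale with the pseudocount, which understates the change of low genes with a peak and, since a missing peak enters as no tags, can overstate that of genes without one. No gene-level fold is given against a group with no peak.

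The 11 lists (T lineage identity, Notch-induced, innate lymphoid and NK, stem and progenitor, B cell, myeloid and dendritic, erythroid and mast, OP9 stromal, mature αβ T, γδ T and housekeeping control) were tested with limma's camera at a preset correlation of 0.01, again with an estimated one, and by Fisher's exact test on regions called in 1 group. Fisher's tests on regions, for lists and for promoters, count regions as independent. Many regions share a gene and neighbouring regions changed together, so those p-values can be too small. The rule for named items was fixed in advance: the 3 title genes, the 5 regions and 10 genes with the largest called change each way whose groups did not overlap, the 5 strongest regions of each group alone, the 5 genes with the most such regions, and up to 4 members of each list by smallest p. Predicted genes were skipped in gene ranks.

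Both tests were tried on simulated data built on the real regions and genes, with 200 changes planted among 20240 regions and 200 among 13675 genes. The real fits called 57.5% of regions and 50.5% of genes. With so few planted changes the adjustment was stricter than in the real data, so the shares below hold for the simulated setting only. For regions, 32.8% of changes of 1 and 82.1% of changes of 2 on the log2 scale were recovered, and none of 0.58, with 1.3% false calls. For genes these shares were 13.4%, 49.3% and none, with 2.3% false calls, so smaller changes can be missed. Alternatives covered pseudocounts, filters on low values, tag density, median-centred and quantile scaling, the replicate number as a block, merging within 1000 bp, start-site distance of 10 kb, and each library left out. Added after the data were seen were limma's trend and voom fits on recovered whole tags, 1 gene per region, removal of stromal-gene regions and left-out libraries for the lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for overlaps, exact tests and figures.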

Results

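H3K27ac, a histone mark of active promoters and enhancers, was profiled by ChIP-seq in mouse pro-T cells with Bcl11b (WT) and in Bcl11b knockout cells (Bcl11bKO). Bcl11b encodes a zinc finger transcription factor that T cell progenitors switch on as they commit to the T lineage. The cells were lineage-negative, Sca1+ Kit+ bone marrow progenitors grown on OP9-DL1, a stromal line that carries a Notch ligand, and their cell type label is DN3, an early thymocyte stage, though the titles and source names of the Bcl11bKO samples leave DN3 out. Each group had 2 libraries, and 4 input samples were not used here. The labels do not say whether the replicates came from separate mice or cultures, so the p-values measure only the spread between these samples, which may be technical.

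The WT libraries listed 31142 and 32022 peaks over 87.1 and 92.7 Mb, and the Bcl11bKO libraries 35086 and 35343 peaks over 92.5 and 100.3 Mb. If the deposited values are tags per 10 M, the library totals were 28.0 and 29.8 M tags in WT and 23.2 and 33.3 M in Bcl11bKO. Of these tags, 35.9% lay in peaks in each WT library, and 39.3% and 40.2% in the Bcl11bKO libraries. Across the 20240 regions called in all 4 libraries, log2 tags correlated at 0.98 within each group and at 0.82 between groups. The replicates differed by more than counting noise, with a standard deviation of the log2 difference of 0.29 in WT and 0.28 in Bcl11bKO against 0.12 from counting in a median region.

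The first comparison asked how H3K27ac changed at the genes in the series title, which names Id2 and Zbtb16 as repressed by Bcl11b. H3K27ac was higher in Bcl11bKO at all of them, the targeted gene included. Bcl11b itself (NM_021399, chromosome 12) carried 1493.8 and 1524.1 normalised tags in WT and 2129.4 and 2332.5 in Bcl11bKO, a rise of 0.56 on the log2 scale (SE 0.06, limma adjusted p = 0.00983), over 40.8 and 59.7 kb of peaks. The labels do not say which part of the gene is deleted, so tags at the locus do not check the genotype. Its peak over the start site (chromosome 12, 109227597-109244827, mm9, annotated as intron) went from 900.4 ± 3.75 to 1175 ± 1.91 tags (SD, n = 2; log2 0.38, SE 0.08, limma adjusted p = 0.0176). Without either WT library the gene's call ended (adjusted p up to 0.0786), and without any 1 of the 4 libraries so did the start-site call (adjusted p up to 0.0734), which also ended after median-centring (log2 0.16).

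Id2 (NM_010496), an inhibitor of E protein transcription factors, rose from 363.3 tags in each WT library to 812.8 and 745.6 in Bcl11bKO (log2 1.08, SE 0.06, limma adjusted p = 0.00316), over 11.9 and 13.7 kb. Its promoter region (chromosome 12, 25776639-25786734, promoter-TSS) accounted for the rise, from 173 ± 25.9 to 682 ± 9.05 tags (SD, n = 2; log2 1.98, SE 0.13, limma adjusted p = 0.00242). A region annotated as intron 40.6 kb from the start site (chromosome 12, 25737560-25742943) fell from 170 to 78.8 tags (limma adjusted p = 0.00857). Zbtb16 (NM_001033324), which encodes PLZF, a transcription factor of innate-like lymphocytes, rose from 290.0 and 308.8 tags to 1513.4 and 1481.3 (log2 2.29, SE 0.04, limma adjusted p = 0.00242), over 15.8 and 53.3 kb. The region spanning its start site (chromosome 9, 48635495-48645480, annotated as exon) rose from 24.1 ± 2.26 to 321 ± 4.67 tags (SD, n = 2; log2 3.68, SE 0.10, limma adjusted p = 0.00221), and an intronic region beside it (48599671-48634960) from 248 ± 11.2 to 1025 ± 17.5 (log2 2.04). Of the 3 regions within 100 kb of Zbtb16 called in all 4 libraries, 1 fell (48563137-48564654). Its call ended with tags per kb of peak (log2 -0.41, limma adjusted p = 0.0847), with limma's trend (adjusted p = 0.0634) and with voom on whole tags (adjusted p = 0.0558). It also ended without WT replicate 2 (log2 -0.46) and without Bcl11bKO replicate 1 or 2 (log2 -0.64 and -0.59). After each library was centred on its median gene, the log2 changes were 0.24 for Bcl11b, 0.76 for Id2 and 1.97 for Zbtb16, all past the threshold.

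**Figure D1:**
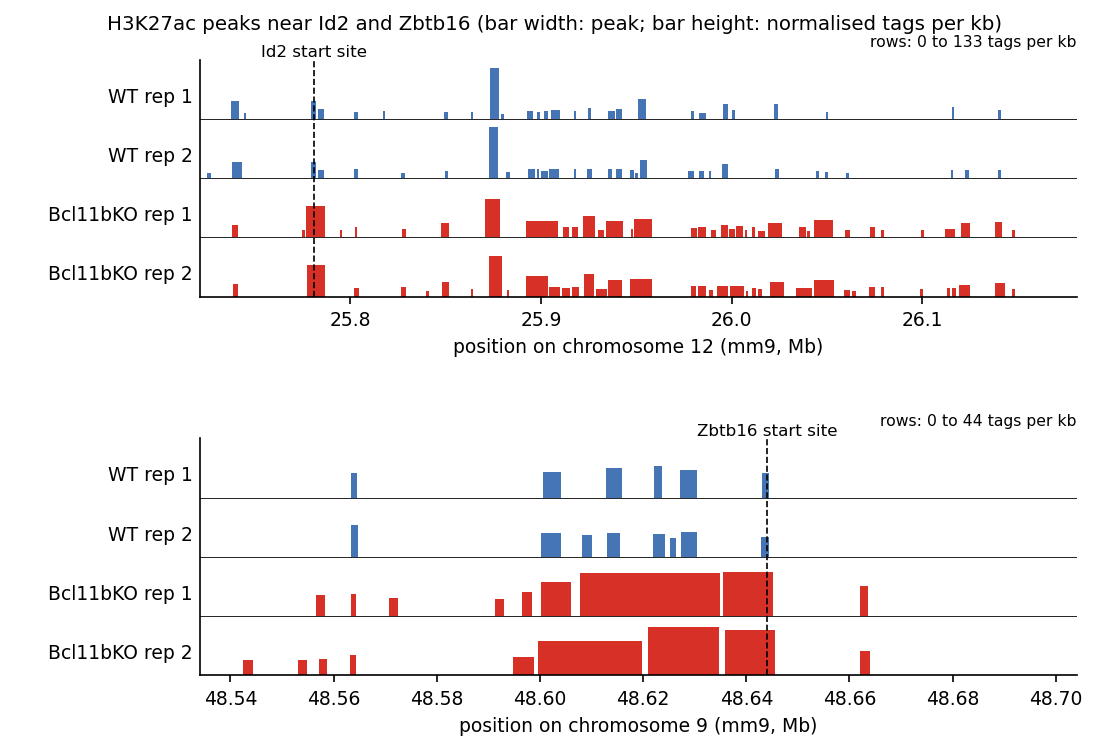
H3K27ac peaks of each library along chromosome 12 near Id2 and chromosome 9 near Zbtb16 (position in Mb, mm9); bar width is the peak and bar height its normalised tags per kb, on 1 scale per panel, and the dashed lines are the start sites. Broad peaks cover the Zbtb16 start site and its neighbouring intron in both Bcl11bKO libraries, where the WT libraries list narrow peaks, and the Id2 promoter peaks are taller and wider in Bcl11bKO.

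The second comparison asked which regions carried a peak in one group alone. Of 44718 merged regions, 20240 were called in all 4 libraries, 5626 in both Bcl11bKO libraries and neither WT library, and 2983 in both WT libraries and neither Bcl11bKO library. The strongest Bcl11bKO region lay over the promoter of Klrk1, which encodes the activating receptor NKG2D (chromosome 6, 129567289-129580120, 610 ± 48.5 tags, SD, n = 2). Next came a region annotated as intron nearest Speer4a (chromosome 5, 26375905-26380915, 429 ± 119.5 tags), a region annotated as exon nearest the NK receptor gene Klrc2 (chromosome 6, 129604723-129614792, 318 ± 24.9), an intergenic region 15.7 kb from the mast cell protease gene Cma1 (chromosome 14, 56544643-56551134, 312 ± 15.2) and an intergenic stretch of 1.0 kb lying 65.0 kb from the complement receptor gene Cr2 (chromosome 1, 197067344-197068429, 311 ± 2.76). The strongest WT regions were annotated as intron and lay nearest Tshz2 (chromosome 2, 169540284-169546631, 246 ± 2.97 tags) and Acsf3 (chromosome 8, 125327266-125336506, 209 ± 28.8). They were followed by an interval of unplaced sequence (chrUn_random, 3770999-3774050, 204 ± 18.2), an intergenic region 2.8 kb from Ybx2 (chromosome 11, 69743454-69749849, 185 ± 33.3) and one 61.4 kb from Tle4 (chromosome 19, 14731940-14735970, 175 ± 5.66).

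Egfr, the epidermal growth factor receptor gene, had 11 regions called in Bcl11bKO alone, followed by Plac9a and Tiam2 with 9 each, Nmnat2 with 7 and the collagen gene Col6a2 with 6. Egfr had no peak in WT and 449 ± 1.34 tags over 27.1 kb in Bcl11bKO, and Col6a2 rose from 17.9 ± 1.48 tags over 1.3 kb to 478 ± 9.47 over 26.3 kb. Tags rose from 68.4 ± 16.1 to 844 ± 18.9 at Tiam2, from 60.6 ± 51.8 to 986 ± 36.2 at Plac9a and from 12.8 ± 18.2 to 456 ± 53.5 at Nmnat2 (SD, n = 2). Those calls ended without either Bcl11bKO library (highest adjusted p 0.0529, 0.158 and 0.155). Tshz2, Atp1a1, Rnf220, Abtb2 and Axdnd1 had the most WT regions, 6 each. Rnf220 fell from 1604 ± 19.6 tags over 51.4 kb to 443 ± 1.84 over 13.3 kb, and Atp1a1, a sodium pump subunit, from 1535 ± 12.2 to 494 ± 28.4. Axdnd1 fell from 1020 ± 14.1 to 460 ± 14.1 tags and Abtb2 from 532 ± 92.9 to 74.0 ± 12.4, the latter no longer called without either Bcl11bKO library (adjusted p up to 0.0581). With only peaks within 10 kb of a start site, Rnf220 stood at 0.13 on the log2 scale (adjusted p = 0.932) and Axdnd1 at -0.38 (adjusted p = 0.0734).

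The other 2 ways of splitting the libraries into pairs gave 710 and 637 such regions, against 8609 for WT and Bcl11bKO. Each of those pairs mixes a WT with a Bcl11bKO library, so a region called by group cannot count there. Low numbers were therefore partly built in, and they give no measure of background. With peaks at or above the median of their list, the counts were 2833 in Bcl11bKO and 1484 in WT, and with the same number of peaks taken from each list they were 4239 and 3635, a smaller imbalance. Without WT replicate 1 or 2, the WT count was 5685 or 4904, and without Bcl11bKO replicate 1 the Bcl11bKO count was 8878. Genes of 2 lists of stromal markers held 109 of the Bcl11bKO regions and 3 of the WT regions. Only regions of listed genes were counted, so these numbers set no bound on how many regions could come from stromal cells. At promoters lay 4.6% of the Bcl11bKO regions and 1.3% of the WT regions (Fisher's exact test, odds ratio 3.63, p = 2.05e-17). Median tags were close, 28.8 and 29.0.

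**Figure D2:**
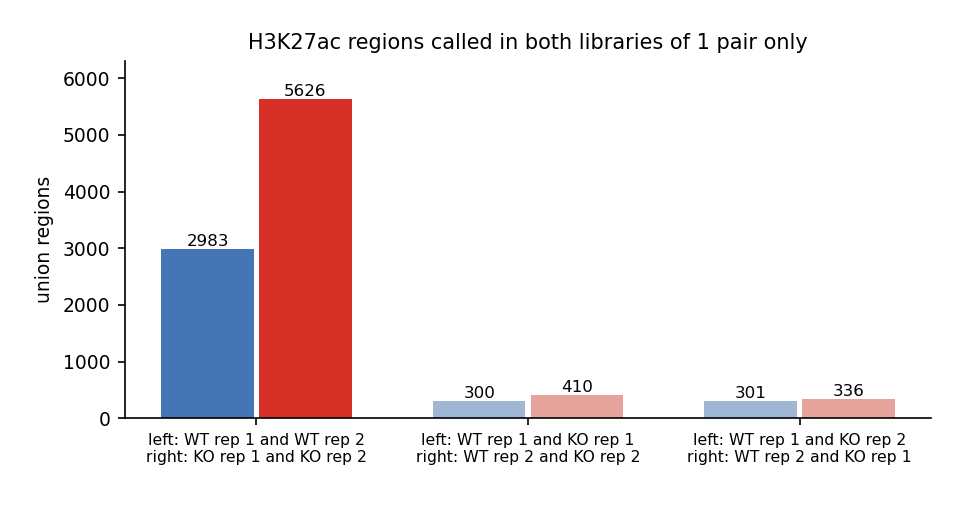
Number of merged H3K27ac regions called in both libraries of a pair and neither of the other pair, for the 3 ways to split the 4 libraries. The WT and Bcl11bKO pairs hold 2983 and 5626 regions, and no other pair holds more than 410. The other pairs mix the groups, so regions called by group cannot count in them.

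The third comparison tested the 20240 regions called in every library. Tags rose in Bcl11bKO at 7799 regions and fell at 3842 (limma, adjusted p under 0.05). The median region was 0.23 higher on the log2 scale in Bcl11bKO and the median gene 0.31 higher, and after each library was centred on its median region 4100 regions rose and 5171 fell. All 4100 of those rises and all 3842 of the first falls were called in the same direction by both fits. Centring lowers the log2 change of every region by the same amount, so this overlap largely follows from the scaling and is no independent check. Promoters made up 24.8% of the regions that rose and 3.6% of those that fell (Fisher's exact test, odds ratio 8.73, p = 7.08e-213), and 20.6% and 5.0% after centring (odds ratio 4.87, p = 2.5e-118).

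An intergenic region 47.1 kb from 4930505K14Rik (chromosome 5, 149619710-149648253) rose most, from 21.8 and 39.9 tags in WT to 1013 ± 18.0 in Bcl11bKO (SD, n = 2; log2 5.05, SE 0.30, limma adjusted p = 0.00223). The next were a region annotated as 3' UTR nearest Gm21671, a member of a multicopy family whose reads may be shared between copies (chromosome 5, 26422718-26427725, log2 4.51), and one annotated as exon nearest Cxcr6, a chemokine receptor gene of NK and innate-like T cells (chromosome 9, 123711613-123728439, from 18.6 and 27.5 tags to 388 ± 33.6, log2 4.04, SE 0.21). An intergenic region 267.4 kb upstream of Id2 (chromosome 12, 26043247-26053491) rose by 3.85 (SE 0.46) and one annotated as intron nearest Dym (chromosome 18, 75253273-75258887) by 3.82 (SE 0.14). The largest fall was intergenic, 36.2 kb from Gm5535 (chromosome 2, 144042596-144058727), from 1122.4 and 1076.0 tags to 42.4 ± 5.23 (log2 -4.67, SE 0.12, limma adjusted p = 0.00221). A region annotated as intron nearest Cd3e, a subunit of the T cell receptor complex (chromosome 9, 44802367-44825410), fell from 849.8 and 853.4 tags over 21.6 kb to 82.7 ± 22.6 over 4.2 kb (log2 -3.38, SE 0.21, limma adjusted p = 0.00225). Regions annotated as intron nearest B4galt4 (chromosome 16, 38755404-38764400), Ap1ar (chromosome 3, 127519697-127531262) and Tpd52 (chromosome 3, 8962513-8971577) showed log2 changes of -3.90, -3.46 and -3.37. All 10 kept their direction and call under every alternative run on them.

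The total depended on the libraries and the measure. The number that rose was 5032 without WT replicate 1, 4882 without WT replicate 2, 4223 without Bcl11bKO replicate 1 and 3800 without Bcl11bKO replicate 2. Tags per kb of peak, in place of summed tags, gave 2960 that rose and 1632 that fell.

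Summed per nearest gene within 100 kb, tags rose at 5142 of 13675 genes and fell at 1766 (limma, adjusted p under 0.05), and after centring at 2620 and 2849, with 22 genes called in opposite directions by these fits. The 10 largest rises and 10 largest falls were all genes with no peak in one group, and for 19 of these 20 the strongest region was called in all 4 libraries but its peaks were assigned elsewhere in one group. For 10 of these 19 those peaks all went to another named gene, and for 9 some or all went to a start site without a gene name in the files. Ifitm5 had no assigned peak in WT and 890 ± 7.35 tags in Bcl11bKO (SD, n = 2), while its region held 538 ± 30.8 tags in WT. Tmem140 had no assigned peak in WT either, and its region held 926 ± 41.6 tags in WT and 1000 ± 24.3 in Bcl11bKO, a log2 change of 0.11 (limma adjusted p = 0.110) with the region held to the gene. After centring, the held log2 change of Tmem140 was -0.20, a called fall (limma adjusted p = 0.0226). That of Ifitm5 was 0.40, still a called rise (limma adjusted p = 0.00607). The other rises by this rule were Tmem254b, Sfxn3, Tmem253, Usp47, Speer4a, Snora24, Rbmxl1 and Atp5h. Held to their regions, Tmem254b (log2 0.80), Usp47 (0.51), Snora24 (0.50), Sfxn3 (0.42), Tmem253 (0.29) and Rbmxl1 (0.21) still rose, but less, and after centring only Tmem254b was called among them, with Tmem253 at -0.02 and Rbmxl1 at -0.10. By contrast, the strongest region of Atp5h fell from 996 to 731 tags (log2 -0.45). The falls were Hist1h2ap, Hist2h3c1, Tmem254a, Max, Aagab, Zfx, Wac, Slc10a7, Gosr1 and Hnrnpll. For 7 of these 10 falls the strongest region itself was higher in Bcl11bKO, a called rise for Tmem254a (log2 0.45) and Hnrnpll (0.39) and uncalled for Hist1h2ap, Hist2h3c1, Zfx, Wac and Slc10a7 (0.10 to 0.26), and only that of Max was a called fall (log2 -0.93). Over the regions held to them, Hnrnpll (log2 -0.98), Gosr1 (-0.44) and Aagab (-0.43) were called falls. For Hnrnpll and Slc10a7 these leave out the strongest region. Slc10a7 was then left with 17.9 tags in WT and no peak in Bcl11bKO, a called fall. Hist1h2ap, Hist2h3c1, Tmem254a, Zfx and Wac had no tested value when held. Without 1 library the calls of Tmem254b, Hist1h2ap and Hist2h3c1 ended (highest adjusted p 0.107, 0.0601 and 0.0603), and Max, held to its region, fell from 758 to 361 tags (log2 -1.05).

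A ranking with every region held to 1 gene was therefore added after the data had been seen. Its largest rises, besides Speer4a, Egfr and the genes of NK receptors Klrk1, Klrc2 and Klrc1, were Cma1, Fam179a, Cr2, Col9a3 and the chloride channel gene Ano1. The Speer4a region lies on chromosome 5 near that of Gm21671, and whether reads shared between copies enter its tags was not tested. Klrk1 rose from 21.4 tags in 1 WT library and no peak in the other to 716 ± 58.8 tags and Ano1 from 12.4 ± 17.5 to 511 ± 6.93 (SD, n = 2), and in the nearest-gene fit, the only one rerun without single libraries, both calls ended without either Bcl11bKO library (highest adjusted p 0.119 and 0.146) or with a pseudocount of 1 (0.0576 and 0.0743). The others had no peak in WT and 303 ± 24.2 tags at Klrc1, 400 ± 5.16 at Cma1, 347 ± 31.3 at Fam179a and 301 ± 11.9 at Col9a3. In that fit Fam179a missed the threshold with peaks within 10 kb (adjusted p = 0.0519). The largest fall was at Tshz2, a zinc finger gene, from 601 ± 31.4 to 7.95 ± 11.2 tags (log2 -5.24, SE 0.56), a call that ended without either WT library in the nearest-gene fit (adjusted p up to 0.0824). Fcrla, Cd6, Gng4, Degs2, Ybx2, Paqr6, Fshr, Cdh5 and Nlrp1a followed, with 141 to 292 tags in WT and no peak in Bcl11bKO. In the nearest-gene fit, the counts of genes that rose without 1 library were 2680 and 2603 without WT replicates 1 and 2 and 2238 and 2112 without Bcl11bKO replicates 1 and 2, and those that fell 906, 892, 1072 and 1134.

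Gene lists for T lineage identity and other cell types had been fixed before the data were examined. Where 5 or fewer members of a list passed in one direction, all are named, and Themis, Tcf7, Tox, Xcl1, Il12rb2, Mycn, Nfe2, Cd79b, Etv5, Gapdh and Eef1a1 among them were named after their values were seen. Of 28 tested T lineage genes, 12 fell in Bcl11bKO, 3 rose and 13 were not called, or 16 falls and 3 rises adjusted over the list alone, with a median log2 change of -0.26. Cd3d, a subunit of the T cell receptor complex, fell from 1467 ± 82.6 to 615 ± 10.4 tags (SD, n = 2; log2 -1.24, SE 0.05), and the costimulatory receptor gene Cd28 from 1322 ± 14.6 to 919 ± 19.5 (log2 -0.52, SE 0.03). Cd6, a T cell surface receptor gene, had 246 ± 1.41 tags in WT and no peak in Bcl11bKO. The 3 that rose were Bcl11b, the adhesion receptor gene Cd2, from 546 ± 19.2 to 974 ± 16.8 tags (log2 0.82, SE 0.04), and Themis, from 1119 to 1355 (log2 0.28, but -0.04 after centring). The list moved down against other genes (limma camera, adjusted p = 5.02e-07), with adjusted p = 0.279 with an estimated correlation. Whole regions were not lost in excess: 6.6% of its 197 regions were called in WT alone against 6.4% of others (Fisher's exact test, odds ratio 1.04, adjusted p = 1.0). In the same libraries 8 of 12 tested stromal genes rose, with a median of 2.27. After centring 21 fell and 2 rose. The numbers that fell were 6 and 5 without WT replicates 1 and 2, and 9 and 8 without Bcl11bKO replicates 1 and 2. Cd28 was not called with peaks within 10 kb (log2 -0.11, adjusted p = 0.452), nor Themis without WT replicate 2 or either Bcl11bKO library (adjusted p up to 0.182).

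Of 11 tested Notch-induced genes, 4 fell and 1 rose, as they did adjusted over the list alone, with a median of -0.24 and a mean of -0.76 (camera adjusted p = 0.0721). With regions held to 1 gene, 2 of 9 rose and 2 fell, with a median of -0.01 and a mean of 0.19 (adjusted p = 0.169), and without either WT library no member was called. Hes1, a Notch target transcription factor, fell from 357 ± 3.82 to 288 ± 4.52 tags (log2 -0.30, SE 0.04), and the interleukin-2 receptor gene Il2ra from 2332 ± 40.2 to 1967 ± 5.30 (log2 -0.24, SE 0.03). Tcf7, which encodes TCF1, fell by 0.18, from 2574 to 2271 tags. Ptcra, the pre-T cell receptor chain, went from 432 ± 42.4 to 9.90 ± 14.0 tags by nearest gene, but its log2 change was -0.01 with regions held to 1 gene (adjusted p = 0.949). Hey1 had no peak in WT and 38.5 ± 16.3 tags in Bcl11bKO. None of the 5 was called in every leave-one-out fit: the highest adjusted p was 0.0609 for Hes1, 0.101 for Il2ra, 0.159 for Tcf7, 0.107 for Ptcra and 0.0976 for Hey1. With peaks within 10 kb, the log2 change was -0.07 for Hes1 (adjusted p = 0.258) and 1.86 for Tcf7 (0.670), and Il2ra missed the threshold (0.167); Tcf7 stood at -0.06 with regions held to 1 gene.

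Of 35 tested innate lymphoid and NK genes, 21 rose and 3 fell, or 21 and 5 adjusted over the list alone, with a median log2 change of 1.08, or 0.89 with genes lacking a peak set to the floor of 15 tags. Zbtb16 (log2 2.29) and Id2 (log2 1.08) were among them. Klrb1b, an NK receptor gene, rose from 1082 ± 31.7 to 1791 ± 16.5 tags (SD, n = 2; log2 0.72, SE 0.03). Eomes, a T-box factor of NK cells, had no peak in WT and 30.8 ± 0.283 tags in Bcl11bKO. The 3 that fell were Tox, from 1483 to 1220 tags (log2 -0.28, but a called rise of 0.34 with peaks within 10 kb, adjusted p = 0.0204), the chemokine gene Xcl1, from 317 to 168 (log2 -0.87), and Il12rb2, from 1014 to 616 (log2 -0.71). Their calls ended in leave-one-out fits, with highest adjusted p of 0.195, 0.165 and 0.0957. The list did not pass against all genes (camera adjusted p = 0.155), but passed after centring (adjusted p = 0.0169), when 19 rose and 5 fell; with an estimated correlation the adjusted p was 0.397. Regions called in Bcl11bKO alone made up 14.7% of its 136 regions and 11.9% of others (Fisher's exact test, odds ratio 1.28, adjusted p = 0.580). Without Bcl11bKO replicate 1 or 2 the numbers that rose were 7 and 8. In the same libraries, 8 of 12 tested stromal genes also rose, with a median of 2.27.

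Of 19 stem and progenitor genes, 6 rose and 5 fell, or 6 and 6 adjusted over the list alone, but 4 rose and 10 fell after centring, with a median of -0.49. Without WT replicate 2 or either Bcl11bKO library 3 rose. In the uncentred fit the median was -0.17 and the mean 0.15, and the test pointed down (camera adjusted p = 0.0819, 0.0366 with regions held to 1 gene and 0.397 with an estimated correlation). Lmo2, a factor of haematopoietic progenitors, had 31.4 ± 0.495 tags in WT and no peak in Bcl11bKO. Mef2c fell from 87.5 ± 1.91 to 18.1 ± 0.636 (log2 -1.79), and Erg, an ETS factor, from 1796 ± 26.7 to 1007 ± 16.3 (log2 -0.83, but 2.84 and not called with peaks within 10 kb). Mycn fell from 321 to 109 tags and Nfe2 from 372 to 173, and neither was called without either WT library (adjusted p up to 0.144 and 0.0607). Meis1, a homeobox gene of stem cells, rose from 217 ± 13.2 to 617 ± 4.17 (log2 1.47, SE 0.06). Of the 59 regions of this list, 16.9% were called in WT alone against 6.4% of other regions (Fisher's exact test, odds ratio 3.0, p = 0.0431 adjusted over 11 lists in both directions). That test counts regions of the same gene as independent, so a value this near the threshold does not settle an excess.

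Markers of the OP9 stromal layer were higher in Bcl11bKO: 8 of 12 tested genes rose and none fell, by both adjustments, with a median log2 change of 2.27. The type I collagen gene Col1a2 rose from 62.6 ± 13.7 tags over 3.4 kb to 679 ± 14.8 over 30.9 kb (SD, n = 2; log2 3.26, SE 0.16). Col3a1 rose from 21.1 ± 5.16 to 239 ± 2.40, Col5a1 from 41.3 ± 9.47 to 391 ± 16.0, and Pdgfra, a receptor of mesenchymal cells, from 16.4 ± 1.41 to 154 ± 8.63. Of the 66 regions of this list, 33.3% were called in Bcl11bKO alone against 11.9% of other regions (Fisher's exact test, odds ratio 3.71, adjusted p = 9.17e-05). The camera adjusted p was 0.0748, 0.00501 after centring, 0.0366 with regions held to 1 gene and 0.397 with an estimated correlation. It was 0.009996 and 0.0268 without WT replicates 1 and 2, and 0.392 and 0.396 without Bcl11bKO replicates 1 and 2, when 2 genes were called. Col1a2, Col3a1 and Col5a1 were not called without either Bcl11bKO library (highest adjusted p 0.0521, 0.0522 and 0.0579).

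The remaining lists went both ways. Among 8 B cell genes, 2 rose and 3 fell, by both adjustments, with a median of -0.45 (camera adjusted p = 0.155, 0.0127 with regions held to 1 gene and 0.397 with an estimated correlation). That median was 0.27 without WT replicate 2 and 0.16 without Bcl11bKO replicate 1, each with 1 fall called. Ebf1, a B lineage factor, rose from 31.9 ± 19.5 to 277 ± 21.9 tags (log2 2.86, SE 0.41), and the coactivator gene Pou2af1 from 793 ± 8.20 to 1444 ± 60.6 (log2 0.86). Fcrla had no peak in Bcl11bKO, the kinase gene Blk fell by 0.35 and Cd79b fell by 1.15. Of 9 myeloid and dendritic genes 3 rose and 1 fell by both adjustments, with a median of 0.23 and a mean of 0.41 while the test pointed down (camera adjusted p = 0.804). That median was 0.74 without WT replicate 1, 0.98 without Bcl11bKO replicate 1 and 0.08 without Bcl11bKO replicate 2, and without either WT library 1 rose. Cebpa, a myeloid factor, had no peak in WT and 83.8 ± 2.62 tags in Bcl11bKO, Cd14 no peak and 28.7 ± 7.07, and Ly6c2 rose from 116 ± 16.1 to 221 ± 25.2, while the integrin gene Itgax had 114 ± 15.3 tags in WT and no peak in Bcl11bKO. In the same libraries 8 of 12 tested stromal genes rose, and these values do not show which cells carried the Ebf1 and Cebpa tags. None of 5 erythroid and mast cell genes passed, with none adjusted over the list alone (median 0.01, mean 0.12, test pointing down, camera adjusted p = 0.599). Their tags in WT and Bcl11bKO were 72.2 and 82.2 at Klf1, 193 and 98.0 at Gypa, 178 and 161 at Tfrc and 26.4 and 113 at Mcpt8. Mcpt8 was called as a rise among genes with a peak in all 4 libraries (adjusted p = 0.0325) and with regions held to 1 gene (0.0128), and Gypa as a fall with regions held to 1 gene (0.00475). Leave-one-out fits ended the calls of Ebf1, Blk, Cd79b, Ly6c2 and Cd14 (highest adjusted p 0.139, 0.133, 0.188, 0.139 and 0.0628), and centring that of Ly6c2 (0.0640).

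Among 8 genes of mature αβ T cells, 2 rose and 2 fell, or 2 and 3 adjusted over the list alone (median -0.03, camera adjusted p = 0.394). After centring 1 rose and 5 fell (median -0.35, adjusted p = 0.0732). Klf2, a regulator of T cell trafficking, rose from 364 ± 2.12 to 1135 ± 33.3 tags (log2 1.62, SE 0.04). Runx3 went from 1326 ± 20.8 to 1472 ± 18.6 (log2 0.15, but a called fall of 0.17 after centring, adjusted p = 0.0231). The coreceptor genes Cd8a and Cd8b1 had 30.1 ± 14.1 and 16.9 ± 0.212 tags in WT, close to the floor of 15, and no peak in Bcl11bKO. Of 7 γδ T cell genes, 4 rose and 2 fell, or 4 and 3 adjusted over the list alone, with a median of 0.55, a mean of -0.22 and a test pointing down (camera adjusted p = 0.804). Sox13, a γδ lineage factor, fell from 637 ± 45.5 to 78.8 ± 17.0 tags (log2 -2.88, SE 0.17), and Blk, on this list too, fell by 0.35. Maf rose by 1.38, Egr3 by 2.11, Id3, an inhibitor of E proteins, by 0.88, and Etv5 by 0.55. Without 1 library the calls of Cd8a, Runx3, Blk and Etv5 ended (highest adjusted p 0.145, 0.131, 0.133 and 0.151), and after centring that of Etv5 (0.251).

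The housekeeping control list moved with the median gene. Of 14 tested, 5 rose and 1 fell, by both adjustments, with a median of 0.27 (camera adjusted p = 0.4297), and after centring 1 rose and 2 fell. Actb rose from 835 ± 33.4 to 1465 ± 40.4 tags (log2 0.80, SE 0.05), Ubc by 0.55, Hsp90ab1 by 0.48, Eef1a1 by 0.54 and Gapdh by 0.23, while Ywhaz fell by 0.22. After centring the values were 0.48 for Actb, 0.23 for Ubc, 0.16 for Hsp90ab1, 0.22 for Eef1a1 and -0.09 for Gapdh, and Ywhaz was a called rise of 0.16 with peaks within 10 kb (adjusted p = 0.0401). Of these only the Actb call held in every leave-one-out fit, with highest adjusted p of 0.0714 for Ubc, 0.120 for Hsp90ab1, 0.171 for Eef1a1, 0.0952 for Gapdh and 0.108 for Ywhaz.

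**Figure D3:**
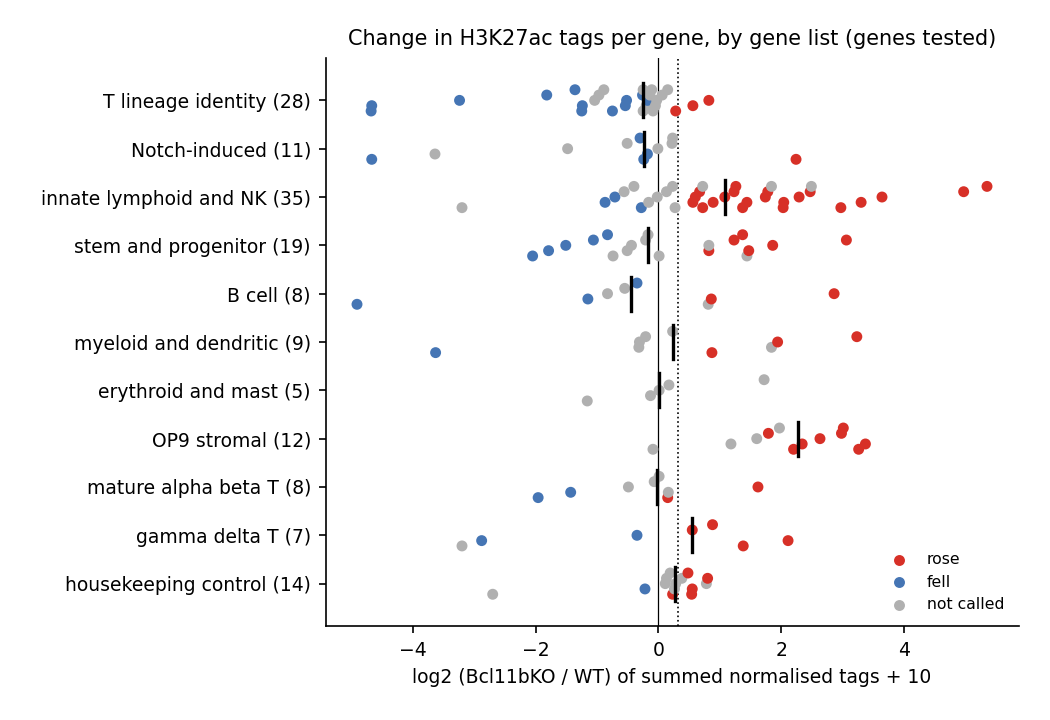
Change in summed H3K27ac tags per tested gene, by list (log2 of Bcl11bKO over WT with a pseudocount of 10); each point is a gene, coloured by whether it rose, fell or was not called, the bars are list medians and the dotted line is the median of all genes (0.31). The medians are -0.26 for T lineage genes, 1.08 for innate lymphoid and NK genes and 2.27 for OP9 stromal genes.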

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

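Tests chosen after the data were seen were limma with a trend, voom on recovered whole tags, 1 gene per region, removal of stromal-gene regions and left-out libraries for the lists. The planned count models on recovered whole tags, edgeR and DESeq2, were not run. The causes of the changes below were not tested, except that a filter changes the number tested. A stricter peak threshold gave 1484 WT and 2833 Bcl11bKO regions, with fewer peaks entering. Median-centring gave 4100 regions that rose, and 2620 genes that rose with 2849 that fell. Regions called in at least 2 libraries gave 11915 rises and 6208 falls of 34122. These include regions called in 1 group only, where a missing peak enters as a filled-in value, not a measured one. The direction of such regions was fixed by how they were selected, so these counts are no separate test of direction. Tag density gave 2960 rises and 1632 falls, and regions at or above the median 2115 falls of 10121. Peaks within 10 kb gave 993 genes that fell. Without 1 library at a time, where the lone sample is assumed to vary like the other group, WT regions numbered 3746 to 5685, Bcl11bKO regions 6601 to 8878, regions that rose 3800 to 5032, regions that fell 2627 to 2982, genes that rose 2112 to 2680 and genes that fell 892 to 1134. The T lineage list lost its call with an estimated correlation (0.279). Centring brought the innate lymphoid and NK list to 0.0169 and the OP9 stromal list to 0.00501, and 1 gene per region brought the stem and progenitor list to 0.0366, the B cell list to 0.0127 and the OP9 stromal list to 0.0366. That list ranged from 0.009996 to 0.396 without 1 library. Signs reversed within 10 kb for Rnf220 (0.13), Erg (2.84), Gypa (0.07), Ywhaz (0.16), Tcf7 (1.86) and Tox (0.34), after centring for Klf1 (-0.15), Runx3 (-0.17), Themis (-0.04) and Gapdh (-0.09), and without WT replicate 1 for Tfrc (0.02, with -0.29 without WT replicate 2). Of these, Ywhaz and Tox within 10 kb and Runx3 after centring were called in the opposite direction (adjusted p = 0.0401, 0.0204 and 0.0231). Of 1088 comparisons over 105 named genes, 933 kept direction and call, 140 lost the call, 4 gained it and 11 reversed, and 40 of the 101 called genes lost a call without 1 library. Of 237 over 17 named regions, 224 kept both and 13 lost the call, at the Bcl11b and Zbtb16 loci.

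With the replicate number as a block, 6518 regions rose and 3557 fell, 3249 genes rose and 1299 fell, no list changed its call, and 13 named genes lost a call and Mcpt8 gained it (adjusted p = 0.0350). The labels give no shared origin for equal numbers, and deviations of equally numbered libraries correlated at 0.02. That value shows no shared deviation, but it cannot exclude that equally numbered samples had a common origin.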

Other observations

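The tests of gene families and of the Id2 flank, and those of the excess of rises and of genes with no peak in one group, were chosen after the results were seen, while those of stromal genes and neighbouring regions were set before their results. Families were compared with all genes after centring, with regions held to 1 gene, over 26 Fisher tests that count neighbouring genes as independent although many lie side by side. The Klr receptor genes of NK cells, on chromosome 6, stood out: 13 of 15 rose and 2 fell, against 24.3% of all genes that rose (adjusted p = 1.67e-05). Klri2 rose from 83.8 ± 3.75 to 429 ± 24.9 tags (SD, n = 2; log2 2.23, or 1.91 after centring). The Gimap GTPase genes, active in lymphocytes and also clustered on chromosome 6, all rose (7 of 7 before centring and 6 of 7 after it, adjusted p = 0.00740), with Gimap3 going from 189 ± 3.11 to 501 ± 5.73. Of 26 collagen genes, 18 rose and 1 fell (adjusted p = 2.15e-05), several of them on the stromal lists. Interferon-induced genes went the other way, with 16 of 28 falling and 1 rising after centring, against 26.5% of all genes that fell (adjusted p = 0.00662), and 9 and 4 before it. Mx1, an antiviral GTPase gene, fell from 66.5 ± 7.28 to 16.9 ± 0.495 tags and Isg20 from 227 ± 1.27 to 130 ± 6.15, though leave-one-out fits ended the calls of both (adjusted p up to 0.0630 and 0.0552). Semaphorin and plexin genes rose more often than others (11 of 23, adjusted p = 0.0392). Histone genes turned with the scaling, with 14 of 35 rising and 2 falling before centring and 2 rising and 18 falling after it, and ribosomal protein genes went from 45 rises and 8 falls of 65 to 13 and 15.

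The stretch 100 to 500 kb upstream of Id2 carried more H3K27ac in Bcl11bKO. Of its 27 regions, 10 of the 12 called in all 4 libraries rose and none fell (9 and none after centring), 9 were called in Bcl11bKO alone and none in WT alone. Summed tags went from 1010.0 over 46.1 kb to 3860.0 over 131.6 kb. On the downstream side at the same distance, none of 6 shared regions rose and 2 fell. Regions called in Bcl11bKO alone were also found in the same stretch upstream of Bcl11b (9 of 22) and downstream of Zbtb16 (7 of 24), with 2 and 1 rises among shared regions. The stretch was tested against nothing else in the genome, and its regions are not known to act on Id2. Neighbouring tested regions within 100 kb changed on the same side of the median in 60.03% of 16240 pairs, against at most 51.4% in 1000 random orders.

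Stromal genes rose with Bcl11b loss, and carried-over OP9-DL1 cells are a candidate source, since the labels name a mesh filter on day 7 and no sort after culture. In a second stromal list of 78 genes, 61 of the 67 tested (91.0%) had both Bcl11bKO libraries above both WT libraries. Chance alone gives 16.7%, all genes 64.2% and 10000 random lists of like level at most 86.6%. The 16.7% does not apply to genes without a WT peak: they were tested only because both Bcl11bKO libraries had one, which fixed that order. Of the 67, 38 also had a peak in both WT libraries, and the share among them is not given here. The median of 2.36 became 2.05 after centring, which follows from lowering every gene by the same amount and is no separate test. Library scaling moves all genes alike, so it is argued against only as the source of the list's distance from the median gene. A rise of silent genes of every tissue stays open, since genes of other tissues had a median 2.12 lower (permutation p = 0.0004) but 8 of the 14 tested had a peak in both WT libraries, and so does activation of stromal genes inside Bcl11b-deficient cells: 58 of the genes rose with regions held to 1 gene, and no value here comes from single cells. The most abundant genes of the second list in Bcl11bKO were Runx2 (1060 tags in WT and 1288 in Bcl11bKO) and Foxc1 (246 and 862), beside 615 at Cd3d and 1791 at Klrb1b in Bcl11bKO.

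More regions rose than fell, and whether the library-size scaling explains it stays open. Rises made up 67.0% of called regions, 44.2% after centring, 53.6% after quantile normalization and 58.0% with voom scaled by tags in tested regions, but these scalings themselves set the balance. The Bcl11bKO library with the fewest tags listed 3064 more peaks than the WT library with the most peaks. This argues against deeper sequencing as the source of that library's longer peak list. Peak numbers do not bear on the balance of rises and falls in normalised tags, so for that balance depth was not tested. A true global gain may also exist, which these files hold no reference for. Splits of the 4 libraries are too few for a share under 0.05. For WT against Bcl11bKO limma called 11641 regions, and 13054 had an unadjusted p under 0.05. Each other split gave 0 calls, with 55 and 31 regions under 0.05. Those splits mix a WT with a Bcl11bKO library in each pair, so the group difference widens their spread. Few calls were therefore fixed in advance there, and the splits give no measure of false calls.

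The largest changes per gene may come from peak assignment: for 19 of the 20 genes the strongest region was called in all 4 libraries, Speer4a being the exception. The regions that held Speer4a peaks still carried a mean of 18.75 tags in WT, against 696.5 in Bcl11bKO. In the group without a peak, the peaks of that region all went to another named gene for 10 of the 19, and some or all to a start site without a gene name for 9, with a median midpoint shift of 402 bp. With regions held to 1 gene, 6593 genes rose and 2081 fell, and 3249 and 3543 after centring. No biological explanation was tested for these 20 genes.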
